A study of Homo sapiens with 6 samples.

How the data were processed

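Total RNA of 786-O cells and of 7R, a line of these cells that the labels call sunitinib-resistant, was sequenced on an Illumina instrument, per the labels, as 3 libraries of each line. The authors deposited a table of raw counts per gene symbol with 1 column per library. Per the submitters' processing notes, HISAT2 2.0.4 was among the tools used. The counting program, its strand setting, the genome build and the annotation are not given in the sources used here, so reads of a gene and of an antisense or overlapping partner may be counted together, reads of near-identical copies may be split between them, and no coordinates are printed. The extraction text in the labels mentions a brain region, while the other labels name 786-O cells. For that reason brain markers were among the lists fixed beforehand.

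Libraries were grouped by their titles and phenotype labels into control and resistant. Each column name equals 1 sample title, and 0 sample columns were left over. Pairs of libraries of a line differed by more than sampling noise (chi-square per degree of freedom 8.94 to 62.9 over genes with at least 20 counts in a pair), so none was treated as a library deposited more than once. This does not show that they came from separate cultures, since library preparation also adds spread. Total counts ranged from 37919629 to 52221491 per library. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

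Genes were kept by edgeR's filterByExpr, which left 16642 of 54261 gene rows. Libraries were scaled by TMM (factors 0.867 to 0.912 in control and 1.12 to 1.14 in resistant libraries), and the 2 groups were compared with edgeR 4.0.16's quasi-likelihood test (R 4.3.3) and Benjamini-Hochberg adjustment at 0.05. No covariate was fitted. Standard errors of log2 fold changes were approximated as the absolute log2 fold change over the square root of F. Gene lists fixed beforehand were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 3 members were tested, with Benjamini-Hochberg adjustment over 36 lists, and again with an estimated correlation and with fry.

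GC content and length were taken from the GENCODE release 29 basic transcripts, as the median over a gene's transcripts, which may differ from the authors' annotation. Of 54261 gene rows, 34719 matched by name, 36 as mitochondrial genes and 1362 by a newer or older symbol, and 18144 did not match or were ambiguous. Of the tested genes 14302 (85.9%) had a value. For the GC and length adjustment, which was chosen after seeing the data, the deviation of each library's log2 CPM (prior count 1) from the gene's mean was fitted with natural splines on GC content (6 degrees of freedom) and log2 length (5), the fit was used as an offset and the TMM factors were recomputed. Where GC content differs between the lines for a biological reason, this adjustment removes that too.

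The genes named in the text follow a rule set before the data were examined. They are the 12 with the largest increase and the 12 with the largest decrease among genes past the threshold with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a clone, LOC, LINC, antisense, open reading frame or pseudogene name. A symbol ending in P and a number counted as a pseudogene name, which also excluded coding genes such as MPP7. To these were added the 5 genes with the largest difference in CPM, up to 4 members of each list with the smallest p (and members against a called list with a smaller p), and 22 genes chosen for sunitinib or renal cancer. Some genes picked by this rule are not reported here.

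The tests were run on simulated counts with the means, dispersions and library sizes of this comparison, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. Over 16233 genes, edgeR recovered 50.7% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 100% of those changed 4-fold, with 14 false calls (7.95% of calls). When the GC and length trend of the data was put into simulated counts of 14063 genes, the unadjusted test called 9950 genes that had not been changed, and the adjusted test called 21 (9.86% of its calls) and recovered 71.6%, 94.0% and 100% of the 3 fold sizes. That trend came from the spline fit that the adjusted test uses, so its removal was built in. It cannot show whether the adjustment is right for these libraries. Far fewer genes were changed than were called in the data (76.2%), so false-call shares may differ there. A list of 20 genes shifted together was called by camera with the preset and with the estimated correlation, and 0 of 56 other lists were called by camera or fry at an adjusted p of 0.05. Simulated genes were drawn independently, so this cannot show how often lists of correlated genes are called in error. In the data, camera with the preset correlation called up to 11 lists in other splits of the libraries. Those splits divide the lines unequally and keep part of the difference between them, so this number is no rate of false calls.

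Alternatives set before the data were examined were DESeq2 size factors, upper-quartile factors and library size alone as scaling, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the robust quasi-likelihood fit, a fit with the replicate number as a block, removal of mitochondrially encoded genes, and leaving out each library. Genes named in the always-reported set without enough counts to be tested are given as counts.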

Results

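RNA from 786-O cells, an established human clear-cell renal carcinoma line, was compared with RNA from 7R, a line of the same cells that the labels call resistant to sunitinib, an inhibitor of the VEGF and PDGF receptors and of KIT, FLT3, CSF1R and RET. Each line was sequenced as 3 libraries, called control and resistant here after the labels. The control libraries held 48264905, 49075320 and 52221491 counts, and the resistant libraries held 38074069, 38131634 and 37919629 counts. A count of 0 in a library allows up to 3 counts, or between 0.0574 and 0.0791 CPM (counts scaled to a common library total) over the 6 libraries, for counting error only. Between 21342 and 21581 genes had counts in the control libraries, and between 22831 and 22988 in the resistant ones. The labels say neither whether sunitinib was present when the cells were harvested nor whether the libraries of a line came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Fold changes below are resistant over control, levels are CPM scaled by TMM factors as mean ± SD, and adjusted p-values come from edgeR's quasi-likelihood test unless another test is named.

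The comparison asked which transcripts differ between the sunitinib-resistant line and the line it came from. Of 16642 genes tested, 6540 were higher and 6143 were lower in the resistant line, together 76.2% of the genes. At least 2-fold changes were found for 4488 higher and 3731 lower genes. The groups did not overlap for 80.3% of the genes tested, where chance gives 10%. The first principal component separated the lines and held 86.7% of the variance. Scaling by library size alone raised the median log2 fold change from 0.05 to 0.39 and the higher genes from 51.6% to 62.5% of the changed genes, so each fold change below is relative to the TMM scale.

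Fold change followed the GC content of the transcripts. Across 14302 tested genes with a GC value, Spearman's rho between log2 fold change and GC content was -0.68, over genes that are not independent replicates. The median log2 fold change fell from 1.31 in the tenth of genes with the lowest GC content to -1.35 in the tenth with the highest. Differences between libraries of the same line also followed GC content, with rho of -0.33, -0.50 and -0.33 for the control pairs and 0.54, 0.49 and -0.13 for the resistant pairs. Resistant replicate 1 stood apart within its line: its pairs gave the values of 0.54 and 0.49 and a chi-square per degree of freedom of 62.9 and 60.1, against 8.94 for the other resistant pair and 12.4 to 35.5 for the control pairs. After a smooth trend on GC content and transcript length was removed from each library, an adjustment chosen after seeing the data, 4870 genes were higher and 4642 lower, of which 2088 and 1206 changed at least 2-fold. Only genes with a GC value entered the adjusted test, and tested without adjustment these gave 3735 genes at least 2-fold higher and 3091 lower. Of 5427 higher and 5752 lower genes called before adjustment that have a GC value, 3453 stayed higher and 3194 stayed lower, 616 turned from higher to lower, 698 turned from lower to higher, and 1358 higher and 1860 lower genes were no longer called. In what follows, values after GC adjustment, or adjusted for GC, are adjusted for GC content and length together unless GC content alone is named.

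**Figure D1:**
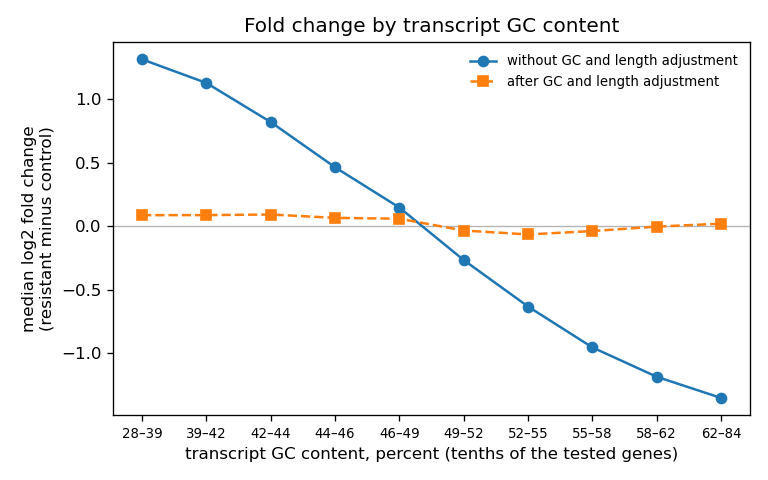
Median log2 fold change (resistant minus control, 3 libraries each) of tested genes in 10 classes of transcript GC content (percent), before adjustment (circles) and after adjustment for GC content and length (squares). The unadjusted medians run from 1.31 to -1.35, and the adjusted medians lie between -0.07 and 0.09.

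The largest increases by the rule fixed beforehand were in INHBE, which encodes an activin beta subunit and rose from 0.210 ± 0.155 to 40.6 ± 14.3 CPM (SD, n = 3), a log2 fold change of 7.57 ± 0.40 (SE, adjusted p = 4.87e-08, adjusted for GC and length 8.26). OSBPL1A, an oxysterol-binding protein family member, rose by 7.45 ± 0.44 on the log2 scale (adjusted for GC 6.89), and CACNB4, a subunit of voltage-gated calcium channels, by 6.94 ± 0.44 (adjusted for GC 5.82). ALDH1L2, a mitochondrial enzyme of folate metabolism, rose from 1.35 ± 0.447 to 54.8 ± 13.2 CPM (adjusted for GC 4.25), and AOAH, an enzyme that deacylates bacterial lipopolysaccharide, rose from 1.44 ± 0.266 to 57.7 ± 9.12 CPM (5.34). PRKAA2, a catalytic subunit of AMPK, rose from 1.26 ± 0.0963 to 39.1 ± 7.91 CPM (adjusted for GC 3.42). KDM7A, a histone demethylase, rose from 2.34 ± 0.0939 to 60.9 ± 5.71 CPM. UNC13C, PCLO and RIMS2, which act in presynaptic vesicle release in neurons, rose by 5.59, 4.89 and 4.68 on the log2 scale (adjusted for GC 4.14, 3.91 and 4.0). SAMD12 and DSP, the desmosomal protein desmoplakin, rose by 4.63 and 4.57 (3.66 and 4.23). All 12 remained higher after the GC and length adjustment, by 3.23 (KDM7A) to 8.26 (INHBE) on the log2 scale.

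The largest decreases included genes that were nearly absent from the resistant libraries. ROR2, a receptor tyrosine kinase that binds Wnt ligands, had 3809 counts over the control libraries and 1 over the resistant ones, a ratio on the TMM scale of 3687 (exact 95% interval 661 to 145673, counting error only). The histone genes HIST1H3C and HIST1H2BB fell from 245 ± 48.3 to 0.186 ± 0.189 CPM and from 11.9 ± 1.40 to 0.0391 ± 0.0491 CPM (adjusted for GC -8.97 and -7.29 on the log2 scale). Histone genes have near-identical copies between which reads may have been split. SYT13, a synaptotagmin, fell from 44.3 ± 2.10 to 0.156 ± 0.0983 CPM, a log2 fold change of -8.13 ± 0.25 (adjusted p = 1.52e-09, adjusted for GC -8.33). S1PR3, a receptor for sphingosine 1-phosphate, had a log2 fold change of -7.32 ± 0.43 (adjusted for GC -7.33), APCDD1L of -6.98 ± 0.25 (-5.86), KRT19, an epithelial keratin, of -6.81 ± 0.25 (-5.46), and SCARA3 of -6.67 ± 0.33 (-5.61). EHD2, an ATPase of caveolae, fell from 223 ± 8.50 to 2.52 ± 0.988 CPM (adjusted for GC -5.19). SPOCD1, the lysosomal nuclease DNASE2 and the receptor GPRC5B had log2 fold changes of -6.42, -6.38 and -6.17 (adjusted for GC -5.23, -5.49 and -5.10). All 12 remained lower after adjustment, by -5.10 (GPRC5B) to -10.53 (ROR2) on the log2 scale.

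In absolute level, the 5 largest differences were all decreases. RN7SK, the small nuclear RNA that holds the elongation factor P-TEFb, fell from 21701 ± 2759 to 6658 ± 949 CPM and was the most abundant gene of each control library (1.70% to 2.09% of counts). The actin genes ACTB and ACTG1 had log2 fold changes of -1.61 and -1.61, the actin cross-linker FLNA of -1.70 and the intermediate filament gene VIM of -2.05. Adjusted for GC and length, these were -0.68 for ACTB, -0.69 for ACTG1, -0.69 for FLNA, -1.34 for VIM and -0.40 for RN7SK, each still past the threshold. ACTB and ACTG1 have processed pseudogenes with which reads may be shared.

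**Figure D2:**
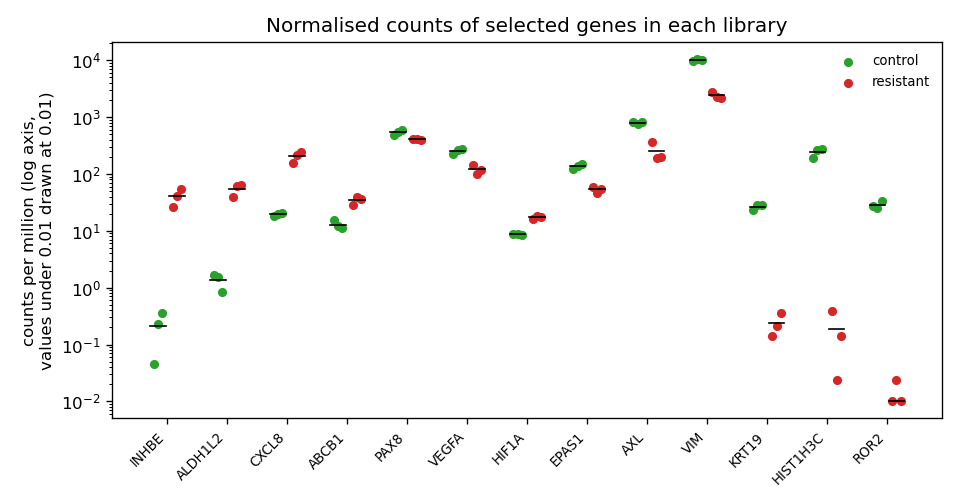
CPM (TMM-scaled, log axis, values under 0.01 drawn at 0.01) of 13 genes named in the text in each of the 3 control and 3 resistant libraries, with a line at each mean. INHBE rises from a mean of 0.210 to 40.6 CPM, PAX8 differs least of the 13 (545 and 407 CPM), and the 2 groups do not overlap for any of the genes drawn.

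Among 36 gene lists fixed beforehand with at least 3 tested members, camera with a preset correlation of 0.01 called 2 higher and 14 lower. With an estimated correlation camera called 0 (3 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 11 higher and 19 lower. After the GC and length adjustment camera called 5 higher and 14 lower, and 0 with an estimated correlation (1 at an unadjusted p under 0.05). Member counts below are over all genes tested; counts adjusted over the list alone equalled them except for lysosome genes (6 higher), TGF-beta targets (12 lower) and apoptosis regulators (10 higher). After GC adjustment the counts adjusted over the list alone differed for fatty acid genes (12 higher), the integrated stress response (19), interferon-stimulated genes (16), inflammatory genes (16), Wnt and Notch genes (0) and apoptosis regulators (3 lower). Camera's direction was down against a positive median for the sunitinib targets (0.98), p53 targets (0.02) and integrins (0.06), and against a positive mean for p53 targets (0.08) and NRF2 targets (0.27). The median turned negative for p53 targets without control replicate 1, control replicate 2 or resistant replicate 3, and for integrins without control replicate 1. Scaled by library size alone, the higher members numbered 8 for HIF targets, 4 for glycolysis, 8 for lysosome, 5 for antigen presentation, 7 for S phase, 5 for mesenchymal genes, 8 for oxidative phosphorylation, 8 for ribosomal proteins and 2 for other receptor kinases. Under the same scaling the lower members numbered 6 for interferon-stimulated genes, 2 each for autophagy, fatty acid and kidney lineage genes and 0 for mitochondrially encoded genes. Other receptor kinases also had 2 higher members with upper-quartile factors, with no low-count filter and by DESeq2. With GC content alone adjusted, the higher members numbered 4 for G2 and M phase, 2 for Wnt and Notch genes, 3 for oxidative phosphorylation and 4 for ribosomal proteins. After GC adjustment with resistant replicate 1 left out, the higher members numbered 3 for G2 and M phase, 0 for Wnt and Notch genes and 2 for endothelial markers, and autophagy had 5 lower.

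**Figure D3:**
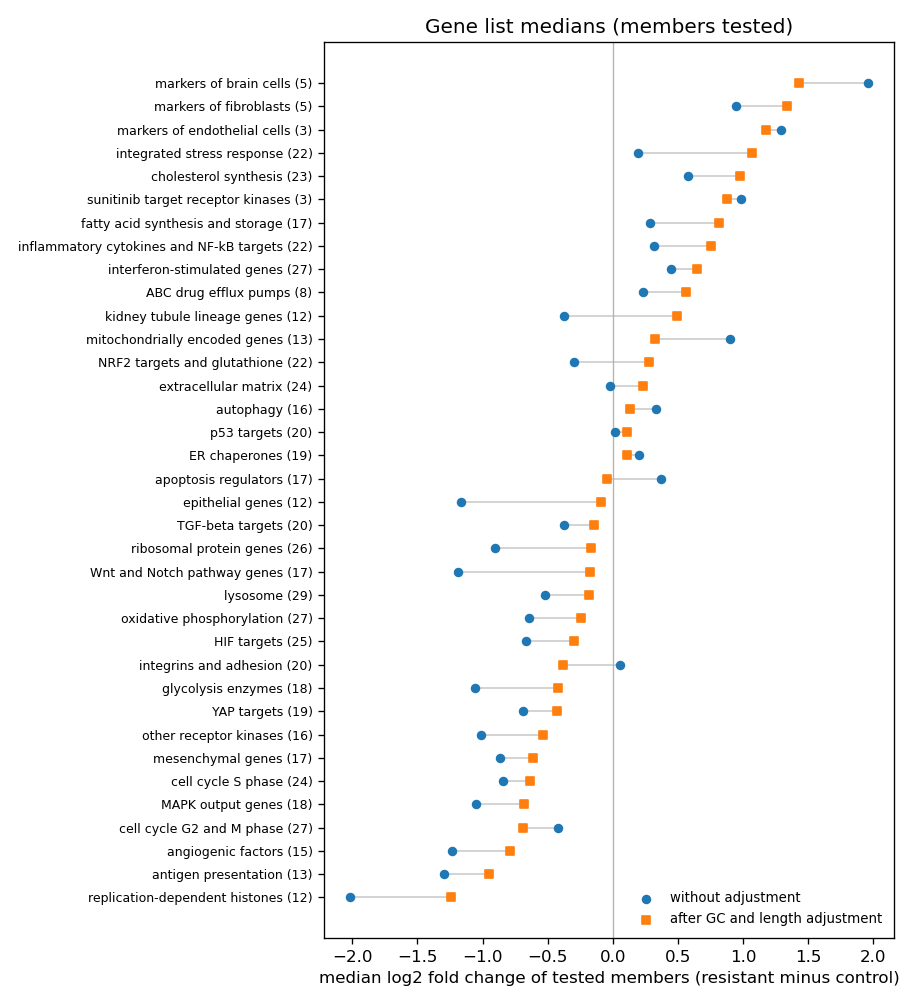
Median log2 fold change (resistant minus control) of the tested members of each of 36 gene lists, before adjustment (circles) and after adjustment for GC content and length (squares), with the number of members tested in parentheses. Replication-dependent histones have the lowest medians (-2.02 and -1.24), and the integrated stress response moves from 0.19 to 1.07.

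The receptors that sunitinib inhibits were low or undetected in both lines. FLT3 and RET had 0 counts in each library. KDR had 26 counts over the control and 21 over the resistant libraries, FLT4 had 7 and 3 (ratio of control to resistant on the TMM scale 2.26, exact 95% interval 0.516 to 13.5), PDGFRA had 8 and 1 (7.74, 1.04 to 344) and KIT had 4 and 1 (3.87, 0.383 to 191), too few to test. At equal library totals the ratio of PDGFRA was 6.10 (0.818 to 271). PDGFRB rose from 4.19 ± 0.611 to 11.5 ± 2.69 CPM, a log2 fold change of 1.45 ± 0.20 (adjusted for GC 2.30), and CSF1R fell from 6.95 ± 1.98 to 0.801 ± 0.282 CPM, a log2 fold change of -3.11 ± 0.30 (adjusted for GC -2.05). FLT1 did not pass the test at 0.211 ± 0.190 and 0.420 ± 0.139 CPM (adjusted p = 0.263). With 1 of 3 tested members higher and 1 lower, the list was not called by camera (adjusted p = 0.957).

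Other receptor kinases were mostly lower, with 11 of 16 tested members lower and 1 higher. The camera adjusted p was 5.98e-04, and the adjusted p = 0.578 with an estimated correlation. After GC adjustment 10 were lower and 4 higher (adjusted p = 0.418 with an estimated correlation). IGF1R fell from 106 ± 7.54 to 18.0 ± 1.09 CPM (adjusted for GC -2.62 on the log2 scale), FGFR1 from 233 ± 19.8 to 56.2 ± 15.2 CPM (-1.29) and ERBB2 from 119 ± 6.72 to 38.3 ± 5.91 CPM (-0.61). AXL, a kinase linked to drug resistance in tumours, fell from 803 ± 37.6 to 253 ± 96.0 CPM, with a log2 fold change of -1.67 ± 0.20 (adjusted for GC -0.68). MET had a log2 fold change of -0.33 ± 0.09 (adjusted p = 0.00652), which became -1.0 after GC adjustment and 0.0091 when scaled by library size alone, where it no longer passed (adjusted p = 0.938).

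In 786-O cells, which lack functional VHL, the hypoxia-inducible factor EPAS1 is active without hypoxia. EPAS1 itself fell from 137 ± 12.7 to 53.7 ± 6.32 CPM (log2 fold change -1.35 ± 0.12, adjusted for GC -1.0). Of 25 tested HIF targets, 16 fell and 5 rose, with a camera adjusted p of 4.08e-04 and an adjusted p = 0.562 with an estimated correlation. Without resistant replicate 3 the higher members numbered 3. After GC adjustment 13 were lower and 6 higher (camera adjusted p = 8.21e-04; adjusted p = 0.363 with an estimated correlation). The collagen cross-linking enzyme LOXL2 fell from 890 ± 69.4 to 95.9 ± 2.23 CPM, the prolyl hydroxylase EGLN3 from 45.8 ± 2.75 to 3.77 ± 0.632 CPM, the glucose transporter SLC2A1 from 1034 ± 140 to 188 ± 27.8 CPM and IGFBP3 from 3820 ± 36.5 to 1165 ± 43.9 CPM. Their adjusted log2 fold changes for GC were -2.23, -3.70, -1.57 and -1.06. VEGFA, the main ligand of the VEGF receptors, fell from 255 ± 24.5 to 122 ± 22.5 CPM (log2 fold change -1.07 ± 0.14), but was higher by 0.24 after GC adjustment (adjusted p = 0.0107). HIF1A turned the other way, from 0.98 ± 0.13 to -0.32 (adjusted p = 0.0377). With GC content alone adjusted, neither VEGFA (0.16, adjusted p = 0.0827) nor HIF1A (-0.29, adjusted p = 0.0540) passed. CA9 had 0 counts in each library. VHL (-0.12 ± 0.11, adjusted p = 0.320) did not pass the test, while after GC adjustment it was lower (-0.36).

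Of 15 tested angiogenic factors, 10 fell and 3 rose (camera adjusted p = 0.0178; adjusted p = 0.562 with an estimated correlation), and after GC adjustment 11 fell and 3 rose (camera adjusted p = 7.51e-04; adjusted p = 0.363 with an estimated correlation). THBS1, an angiogenesis inhibitor in the list, fell from 2086 ± 135 to 430 ± 16.8 CPM (adjusted for GC -2.86 on the log2 scale). PDGFB and VEGFB had log2 fold changes of -2.60 and -2.22 (adjusted for GC -1.36 and -0.79), and PDGFA of -1.51 (-0.49). CXCL8, a chemokine, rose against the list from 19.6 ± 1.16 to 205 ± 44.2 CPM (log2 fold change 3.39 ± 0.16, adjusted for GC 2.25).

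Of 22 tested genes of the integrated stress response, a programme driven by ATF4, 10 rose and 5 fell (camera adjusted p = 0.0465; adjusted p = 0.653 with an estimated correlation). The median of 0.19 became 0.08 without control replicate 1 and 0.12 without control replicate 3. The call was lost without control replicate 1 (adjusted p = 0.125), without control replicate 2 (median 0.25, adjusted p = 0.0528) and with a filter of 1 CPM in 3 libraries (median 0.24, adjusted p = 0.0560). After GC adjustment 18 rose and 3 fell (camera adjusted p = 7.77e-08; adjusted p = 0.363 with an estimated correlation). SLC7A11, the cystine transporter, rose from 42.3 ± 1.12 to 553 ± 129 CPM, asparagine synthetase ASNS from 47.3 ± 4.16 to 181 ± 23.0 CPM and the mitochondrial folate enzyme MTHFD2 from 97.1 ± 8.95 to 279 ± 11.8 CPM. Adjusted for GC, their log2 fold changes were 2.15, 1.45 and 0.68.

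Of 23 tested cholesterol synthesis genes, 13 rose and 7 fell, and the list was not called before adjustment (camera adjusted p = 0.130). After GC adjustment 18 rose and 3 fell (camera adjusted p = 5.63e-04; adjusted p = 0.490 with an estimated correlation), and the list was called without adjustment when resistant replicate 1 was left out (adjusted p = 0.00593) or no low-count filter was used (adjusted p = 0.0325). Over all filtered genes and libraries the unadjusted list had an adjusted p = 0.653 with an estimated correlation. HMGCS1, which makes HMG-CoA, rose from 25.6 ± 0.869 to 203 ± 77.2 CPM, SC5D from 13.5 ± 2.15 to 78.0 ± 21.8 CPM, STARD4 from 8.64 ± 0.165 to 52.6 ± 17.5 CPM and MSMO1 from 25.9 ± 1.33 to 109 ± 28.9 CPM. Their adjusted log2 fold changes for GC were 1.81, 1.35, 1.53 and 0.94. Resistant replicate 1 held 4914 counts of HMGCS1, and the other resistant libraries 10722 and 10370. Fatty acid synthesis and storage genes gave 10 higher and 4 lower of 17 tested (camera adjusted p = 0.323), and 11 higher and 2 lower after GC adjustment (camera adjusted p = 0.0138; adjusted p = 0.490 with an estimated correlation). SCD, the stearoyl-CoA desaturase, rose from 89.2 ± 2.38 to 456 ± 182 CPM (adjusted for GC 2.05), and ACSL3 and ME1 had log2 fold changes of 2.34 and 1.70 (adjusted for GC 1.12 and 0.51). PLIN3, a lipid droplet protein, fell by 1.43 on the log2 scale (adjusted for GC -0.32).

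Drug efflux pumps moved both ways, with 4 of 8 tested members higher and 2 lower (camera adjusted p = 0.634; 5 and 3 after GC adjustment). ABCB1, which encodes P-glycoprotein, rose from 12.9 ± 2.27 to 34.5 ± 5.45 CPM (log2 fold change 1.42 ± 0.16, adjusted for GC 0.62). ABCC2 rose from 2.93 ± 0.931 to 32.6 ± 1.27 CPM and ABCC4 from 66.7 ± 4.84 to 161 ± 19.0 CPM (adjusted for GC 2.89 and 0.71), while ABCC3 fell from 89.3 ± 12 to 11.5 ± 1.07 CPM (adjusted for GC -1.79). ABCG2 had a log2 fold change of -0.18 ± 0.34 (adjusted p = 0.649), and of -1.35 after GC adjustment (adjusted p = 0.00374). Lysosomal genes, among them acid hydrolases and proton pump subunits, were lower for 17 of 29 tested members and higher for 5 (camera adjusted p = 0.00706; adjusted p = 0.585 with an estimated correlation). After GC adjustment 14 were lower and 3 higher (adjusted p = 0.490 with an estimated correlation), a call lost when resistant replicate 1 was also left out (median -0.18 with it and -0.29 without it, adjusted p = 0.0696). CTSB, a cysteine protease, and NPC2, which carries cholesterol, had log2 fold changes of -1.57 and -1.77 (adjusted for GC -0.70 and -1.65). SMPD1 and ATP6V0D1 had log2 fold changes of -1.77 and -1.87 (adjusted for GC -0.53 and -0.81). Autophagy genes were not called, with 8 higher and 4 lower of 16 (camera adjusted p = 0.506; 7 and 3 after GC adjustment). NBR1 and OPTN, cargo receptors, had log2 fold changes of 0.82 and 0.84 (adjusted for GC 0.75 and 0.34), ATG12 turned from 0.97 to -0.25, and TFEB (-1.45) was no longer called after GC adjustment (-0.08). ER chaperones gave 9 higher and 5 lower of 19 (camera adjusted p = 0.847; 7 and 6 after GC adjustment). CALR, CRELD2 and PDIA4 had log2 fold changes of -0.97, -1.72 and -0.81 (adjusted for GC -0.26, -0.48 and -0.29), and CANX went from 0.88 to -0.14 (adjusted p = 0.0720). With resistant replicate 1 also left out CANX was called lower (-0.17, adjusted p = 0.0160).

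In the S-phase list 16 of 24 tested members fell and 2 rose (camera adjusted p = 9.80e-04; adjusted p = 0.578 with an estimated correlation), and after GC adjustment 21 fell and 1 rose (adjusted p = 0.363 with an estimated correlation). Without control replicate 2 the higher members numbered 1. The replication licensing factor CDT1 fell from 136 ± 8.99 to 24.5 ± 5.61 CPM, GINS2 from 90.8 ± 9.23 to 22.5 ± 1.01 CPM and MCM5 from 326 ± 30.7 to 83.6 ± 18.0 CPM (adjusted for GC -1.15, -1.93 and -0.95 on the log2 scale), and E2F1 had a log2 fold change of -1.52 (adjusted for GC -0.20). Of 27 tested genes of G2 and M phase, 14 fell and 10 rose (camera adjusted p = 0.289), while after GC adjustment 20 fell and 1 rose (camera adjusted p = 3.52e-05; adjusted p = 0.363 with an estimated correlation). The mitotic kinase PLK1 fell from 864 ± 92.3 to 223 ± 46.4 CPM, CDCA8 from 212 ± 8.58 to 62.6 ± 10.1 CPM, AURKB from 114 ± 11.3 to 40.6 ± 3.57 CPM and BIRC5 from 293 ± 9.29 to 108 ± 16.2 CPM (adjusted for GC -0.94, -1.42, -0.52 and -0.97). All 12 replication-dependent histones of the list fell before and after GC adjustment (camera adjusted p = 2.26e-06; adjusted p = 0.585 with an estimated correlation, and 0.490 after GC adjustment). HIST1H1B and HIST2H2AC fell from 1444 ± 238 to 303 ± 82.1 CPM and from 1239.9 ± 222 to 313 ± 59.3 CPM (adjusted for GC -1.0 and -0.45), and HIST1H2BK and HIST2H2BE had log2 fold changes of -1.90 and -2.05 (adjusted for GC -0.44 and -2.04).

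The p53 targets split, with 9 higher and 9 lower of 20 (camera adjusted p = 0.993; 8 and 5 after GC adjustment). RRM2B and TP53INP1 rose by 2.24 and 2.99 on the log2 scale (adjusted for GC 1.39 and 1.70), and DDB2 and FDXR had log2 fold changes of -1.41 and -1.78 (adjusted for GC -0.59 and -0.36). Apoptosis regulators gave 9 higher and 5 lower of 17 (camera adjusted p = 0.557; 4 and 4 after GC adjustment). The pro-apoptotic gene PMAIP1 had a log2 fold change of 1.49 (adjusted for GC 0.65), the anti-apoptotic BCL2L1 of -1.20 (-0.29), and XIAP, at 1.47, was not called after GC adjustment (0.03) but was with GC content alone adjusted (0.26, adjusted p = 0.00816).

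Interferon-stimulated genes rose for 13 of 27 tested members and fell for 10, with a camera adjusted p of 0.0793. After GC adjustment 15 rose and 3 fell (camera adjusted p = 0.00167; adjusted p = 0.363 with an estimated correlation), and the list was called without adjustment when resistant replicate 1 was left out (adjusted p = 0.0404) or no low-count filter was used (adjusted p = 0.0325). The unadjusted median of 0.44 lay between 0.16 and 0.46 with each library left out in turn, and over all libraries the adjusted p = 0.585 with an estimated correlation. XAF1 rose from 1.47 ± 0.362 to 25.9 ± 3.42 CPM, IFI44L from 2.30 ± 0.400 to 37.1 ± 13.3 CPM and DDX60 from 6.46 ± 0.0911 to 36.0 ± 8.52 CPM (adjusted for GC 3.68, 2.60 and 1.12 on the log2 scale). Inflammatory cytokines and NF-kB targets gave 9 higher and 9 lower of 22 (camera adjusted p = 0.506), and 15 higher and 2 lower after GC adjustment (camera adjusted p = 0.00164; adjusted p = 0.50 with an estimated correlation). CXCL5 rose from 11.7 ± 3.16 to 231 ± 56.8 CPM, BIRC3 from 28.4 ± 5.24 to 245 ± 52.1 CPM and VCAM1 from 22.1 ± 3.37 to 77.2 ± 4.80 CPM (adjusted for GC 3.08, 1.81 and 0.84), while CSF1 had a log2 fold change of -1.39 (adjusted for GC -0.24). IL6 did not pass the test at 20.8 ± 3.88 and 20.2 ± 5.63 CPM (adjusted p = 0.848). Antigen presentation genes were lower for 8 of 13 tested members and higher for 1 (camera adjusted p = 0.0124; adjusted p = 0.587 with an estimated correlation), and after GC adjustment 9 were lower and 2 higher (adjusted p = 0.508 with an estimated correlation). The call was lost without resistant replicate 1, before (median from -1.29 to -0.80, adjusted p = 0.0825) and after GC adjustment (from -0.95 to -0.63, adjusted p = 0.103). The class I transactivator NLRC5 fell from 29.3 ± 3.15 to 1.96 ± 0.378 CPM (adjusted for GC -3.08), HLA-B, whose reads may be split with similar class I genes, had a log2 fold change of -2.24 (adjusted for GC -0.95), and PSMB10 of -1.78 (-0.50).

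Of 17 tested mesenchymal genes, 10 fell and 3 rose (camera adjusted p = 0.00461; adjusted p = 0.562 with an estimated correlation), and 10 fell and 2 rose after GC adjustment (adjusted p = 0.363 with an estimated correlation). The smooth-muscle actin-binding gene TAGLN fell from 153 ± 20.5 to 5.92 ± 0.610 CPM, the transcription factor FOXC2 from 7.46 ± 0.192 to 0.225 ± 0.0864 CPM and the membrane protease MMP14 from 776 ± 91.8 to 215 ± 17.2 CPM (adjusted for GC -3.53, -3.78 and -0.82). Among YAP targets 12 of 19 fell and 5 rose (camera adjusted p = 0.0243; adjusted p = 0.578 with an estimated correlation), and 11 fell and 4 rose after GC adjustment (adjusted p = 0.363 with an estimated correlation). Without adjustment the median was -0.69. The call was lost when scaled by library size alone (median -0.35, adjusted p = 0.0681), with a filter of 1 CPM in 3 libraries (-0.65, adjusted p = 0.0560) and over genes with a GC value only (-0.61, adjusted p = 0.0566). Without control replicate 2 the higher members numbered 3. F3, which encodes tissue factor, fell from 93.2 ± 12.5 to 14.9 ± 0.787 CPM (adjusted for GC -3.33), and MYOF, DLC1 and GADD45B had log2 fold changes of -1.86, -1.46 and -1.80 (adjusted for GC -2.16, -1.47 and -0.61). MAPK output genes were lower for 13 of 18 tested and higher for 2, or 1 without control replicate 2 (camera adjusted p = 0.0270; adjusted p = 0.653 with an estimated correlation). The median was -1.05. The call was lost with the filter of 1 CPM (median -0.87, adjusted p = 0.0560), over genes with a GC value only, before adjustment (-0.98, adjusted p = 0.0552) and after it (-0.68, 10 lower and 4 higher, adjusted p = 0.0631). After GC adjustment the adjusted p = 0.540 with an estimated correlation, and by camera with resistant replicate 1 left out the list was called lower (median from -0.68 to -0.87, adjusted p = 0.0243). Cyclin D1 (CCND1) fell from 887 ± 42.2 to 288 ± 23.4 CPM and FOSL1 from 283 ± 49.4 to 54.2 ± 13.4 CPM (adjusted for GC -0.62 and -1.13), and EPHA4 and PHLDA1 had log2 fold changes of -1.33 and -1.38 (adjusted for GC -1.40 and -2.26).

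Of 17 tested Wnt and Notch pathway genes, 11 fell and the others did not pass (camera adjusted p = 5.98e-04; adjusted p = 0.578 with an estimated correlation), and 8 fell and 1 rose after GC adjustment (adjusted p = 0.363 with an estimated correlation). With upper-quartile factors or the filter of 1 CPM 1 member rose, and with library size alone 2 did. LEF1, a Wnt transcription factor, had 715 counts over the control and 2 over the resistant libraries, a ratio on the TMM scale of 346 (exact 95% interval 95.5 to 2863; log2 fold change adjusted for GC -7.92). WNT7B fell from 164 ± 12.3 to 7.62 ± 3.69 CPM (adjusted for GC -3.05), and NOTCH1 and DKK3 had log2 fold changes of -1.63 and -1.68 (adjusted for GC -0.62 and -0.95). TGF-beta targets gave 11 lower and 5 higher of 20 and were not called (camera adjusted p = 0.0996; 9 and 4 after GC adjustment). They were called lower with no low-count filter (adjusted p = 0.0213). With the filter the adjusted p = 0.578 with an estimated correlation, and 0.397 after GC adjustment. THBS1 was also a member of this list, and BAMBI and ID1 had log2 fold changes of -1.45 and -1.35 (adjusted for GC -0.72 and -0.22). Integrins and adhesion genes gave 8 higher and 8 lower of 20 (camera adjusted p = 0.312). The list's median (0.06) was positive while camera's direction was down. After GC adjustment 11 fell and 4 rose (camera adjusted p = 0.0132; adjusted p = 0.490 with an estimated correlation), a call lost when resistant replicate 1 was also left out (median -0.38 with it and -0.40 without it, adjusted p = 0.0531). T-cadherin CDH13 fell from 45.1 ± 5.29 to 0.741 ± 0.378 CPM (adjusted for GC -6.10), and ITGA3, ITGA5 and ITGB3 had log2 fold changes of -2.27, -1.61 and -1.26 (adjusted for GC -1.19, -0.65 and -0.89).

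Extracellular matrix genes were not called, with 11 lower and 6 higher of 24 (camera adjusted p = 0.323), and the median of -0.02 turned to 0.32 when scaled by library size alone, to 0.04 with upper-quartile factors, and to 0.03 without resistant replicate 3. After GC adjustment 9 were lower and 10 higher, with a median of 0.23 against camera's downward direction (adjusted p = 0.740). FBN1 and COL6A1 fell from 15.5 ± 1.31 to 1.46 ± 0.413 CPM and from 17.5 ± 1.54 to 1.99 ± 0.212 CPM (adjusted for GC -4.06 and -1.85), LUM rose from 1.69 ± 0.149 to 30.3 ± 12.4 CPM (adjusted for GC 2.86), and COL6A2 (-1.49) was no longer called after GC adjustment (-0.17). Epithelial genes gave 7 lower and 5 higher of 12 (camera adjusted p = 0.322; 4 and 3 after GC adjustment), with KRT19, KRT8 (-1.96, adjusted for GC -0.74) and CLDN4 (-1.30, adjusted for GC -0.41) lower and DSP higher. Kidney tubule lineage genes gave 4 lower and 3 higher of 12 (camera adjusted p = 0.620; 1 and 5 after GC adjustment), and 1 higher without resistant replicate 3. PAX8, a renal lineage transcription factor, had a log2 fold change of -0.42 ± 0.10 (adjusted p = 0.00202), which was not called when scaled by library size alone (-0.07, adjusted p = 0.50) and turned to 0.45 after GC adjustment. PAX2, at -1.10, was not called after GC adjustment (0.13). It was called higher with resistant replicate 1 also left out (0.20, adjusted p = 0.0298) and with GC content alone adjusted (0.26, adjusted p = 0.0331). CUBN rose from 1.06 ± 0.285 to 4.97 ± 0.900 CPM (adjusted for GC 1.61).

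Glycolytic enzymes were lower for 14 of 18 tested and higher for 1 (camera adjusted p = 1.93e-04; adjusted p = 0.587 with an estimated correlation), and 12 fell and 2 rose after GC adjustment (adjusted p = 0.50 with an estimated correlation). ALDOA fell from 3619 ± 334 to 859 ± 168 CPM and PFKP from 1705 ± 132 to 488 ± 49.4 CPM (adjusted for GC -0.78 and -0.81), ENO2 had a log2 fold change of -2.85 (-2.05) and PFKL of -1.81 (-0.28). Nuclear genes of oxidative phosphorylation were lower for 17 of 27 and higher for 5 (camera adjusted p = 0.0332; adjusted p = 0.653 with an estimated correlation), and 15 fell and 5 rose after GC adjustment (adjusted p = 0.496 with an estimated correlation). Without adjustment the median was -0.64. The call was lost when scaled by library size alone (median -0.30, adjusted p = 0.0879), with the filter of 1 CPM (-0.60, adjusted p = 0.0560) and over genes with a GC value only (-0.56, adjusted p = 0.0785). Without control replicate 3 the higher members numbered 3. SDHC, UQCRC1 and COX4I1 had log2 fold changes of -1.41, -1.48 and -1.30 (adjusted for GC -1.0, -0.28 and -0.53), and NDUFV1 went from -1.18 to 0.10 (adjusted p = 0.209). Of the 13 mitochondrially encoded genes, 11 rose and 1 fell (camera adjusted p = 0.0178; adjusted p = 0.653 with an estimated correlation), and the call was lost after GC adjustment (6 and 2, adjusted p = 0.0729). Without resistant replicate 1 the lower members numbered 2. Mitochondrial transcripts made up 2.57% to 3.19% of counts in the control and 4.78% to 4.98% in the resistant libraries. ND1 rose from 1599 ± 252 to 5972 ± 192 CPM (adjusted for GC 1.93), ND2 and ND4L had log2 fold changes of 1.69 and 1.38 (adjusted for GC 1.09 and 0.97), and ND3, at 0.92, was not called after GC adjustment (0.10). ND3 was called higher with resistant replicate 1 also left out (0.16, adjusted p = 0.0414) and lower with GC content alone adjusted (-0.19, adjusted p = 0.0465). Ribosomal protein genes were lower for 17 of 26 and higher for 3 (camera adjusted p = 0.00706; adjusted p = 0.653 with an estimated correlation), and the call was lost after adjustment for GC content and length (13 and 7, adjusted p = 0.255) but not with GC content alone adjusted (adjusted p = 0.0483). RPL13, RPS2 and RPL35 had log2 fold changes of -1.62, -1.60 and -1.47 (adjusted for GC -0.67, -0.30 and -0.27), and RPLP2 turned from -1.17 to 0.24 (0.12 with GC content alone adjusted, adjusted p = 0.161). Targets of NRF2 and glutathione genes gave 11 lower and 6 higher of 22 (camera adjusted p = 0.859), with a median of -0.29 that became 0.05 when scaled by library size alone, and 3 lower and 13 higher after GC adjustment (adjusted p = 0.0650, and 0.0333 with resistant replicate 1 also left out, called higher; over all libraries adjusted p = 0.508 with an estimated correlation). NQO1 fell from 223 ± 17.2 to 79.4 ± 2.78 CPM (adjusted for GC -1.42). SLC7A11 and ABCC2, which are also members of this list, had log2 fold changes of 3.71 and 3.48 (adjusted for GC 2.15 and 2.89).

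Of 15 brain markers 5 were tested, of which 4 rose and 1 fell (camera adjusted p = 0.225; 4 and 1 after GC adjustment). MBP, the most abundant, rose from 25.1 ± 2.44 to 39.4 ± 1.77 CPM, SNAP25 from 3.32 ± 0.460 to 12.9 ± 1.68 CPM and SYT1 from 0.405 ± 0.128 to 2.29 ± 0.723 CPM (adjusted for GC 1.68, 1.29 and 1.43), and GAD1 had a log2 fold change of -1.20 (adjusted for GC -0.82). AQP4 had 0 counts over the control and 46 over the resistant libraries, at least 15.8-fold higher on the TMM scale against a floor of 3 counts over the group. The list's median (1.96, that of SNAP25) is the same with AQP4 at that bound. Of the endothelial markers 3 were tested (camera adjusted p = 0.599; 1 higher after GC adjustment). ROBO4 rose from 0.340 ± 0.0749 to 1.57 ± 0.394 CPM (adjusted for GC 3.33), while PECAM1 (adjusted p = 0.132) and ESAM (adjusted p = 0.984) did not pass. By limma-voom PECAM1 was called higher (2.25, adjusted p = 0.0447). After GC adjustment with resistant replicate 1 left out ESAM was called higher (1.60, adjusted p = 0.0326). Only 2 immune markers were tested, too few for a set test. CD68 fell from 42.1 ± 3.79 to 9.24 ± 0.962 CPM (adjusted for GC -1.30), and CSF3R did not pass (adjusted p = 0.665). Of 5 tested fibroblast markers, LUM and PDGFRB rose and COL1A1 fell, with a log2 fold change of -0.89 (adjusted for GC 0.12, not called), COL3A1 did not pass (adjusted p = 0.262), and the list was not called (camera adjusted p = 0.323, and 0.0729 after GC adjustment). After GC adjustment with resistant replicate 1 left out it was called higher (adjusted p = 0.0250). Over all libraries the adjusted p = 0.653 with an estimated correlation, and 0.490 after GC adjustment.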

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

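Alternatives that adjust for GC content, use only genes with a GC value or leave out resistant library 1 after adjustment were chosen after seeing the data. The direction and call of the 166 tested genes named were the same under DESeq2 size factors, upper-quartile factors, no low-count filter, the robust fit, each library left out, and DESeq2. They were the same for 164 with library size alone, 165 with limma-voom (all but PECAM1) and 151 after GC and length adjustment. A gene called in neither fit counted as the same whatever its sign. Such genes, among them ESAM (1.09 after GC and length adjustment), are left out of the opposite signs listed below. Leaving out each library gave 6179 to 6789 genes higher, 5894 to 6410 lower, 4307 to 4832 over 2-fold higher, 3600 to 4146 over 2-fold lower, 1 to 4 lists higher and 13 to 14 lower. The replicate numbers did not pair the libraries (same-number correlations of -0.15, -0.02 and -0.07), and with the replicate block 6246 genes were higher, 5851 lower, 4400 and 3692 over 2-fold, and 2 lists higher and 14 lower, with no call of a named gene or list changed. Depth limits the receptors with few counts, such as KIT and PDGFRA, whose ratios have wide intervals.

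With library size alone 2276 genes were over 2-fold lower and the log2 fold change of MET was 0.0091. The lists higher numbered 4 with no low-count filter, 1 with the filter of 1 CPM, 1 without mitochondrially encoded genes (that list is then absent) and 11 by fry. By camera with an estimated correlation 0 lists were higher and 0 lower. Over genes with a GC value only and without adjustment, 3735 genes were over 2-fold higher and 3091 over 2-fold lower, and 2 lists were higher and 11 lower. After GC and length adjustment, 2088 genes were over 2-fold higher and 1206 over 2-fold lower, and 5 lists were higher and 14 lower. Log2 fold changes with the opposite sign were ATG12 -0.25, CANX -0.14, NDUFV1 0.10, RPLP2 0.24, PAX2 0.13, PAX8 0.45, COL1A1 0.12, HIF1A -0.32 and VEGFA 0.24. After adjustment for GC alone, 2077 genes were over 2-fold higher and 1278 over 2-fold lower, and 5 lists were higher and 15 lower. Log2 fold changes with the opposite sign were ATG12 -0.28, CANX -0.068, NDUFV1 0.034, ND3 -0.19, RPLP2 0.12, PAX2 0.26, PAX8 0.55, COL1A1 0.36, HIF1A -0.29 and VEGFA 0.16. After GC and length adjustment with resistant library 1 left out, 2291 genes were over 2-fold higher and 1391 over 2-fold lower, and 7 lists were higher and 12 lower. Log2 fold changes with the opposite sign were ATG12 -0.28, CANX -0.17, NDUFV1 0.073, RPLP2 0.26, PAX2 0.20, PAX8 0.50, ESAM 1.60, COL1A1 0.0059, HIF1A -0.42 and VEGFA 0.20. The median of the NRF2 targets was 0.30 (adjusted p = 0.0333). After GC and length adjustment with the replicate block, 2013 genes were over 2-fold higher and 1183 over 2-fold lower, and 6 lists were higher and 14 lower. Log2 fold changes with the opposite sign were ATG12 -0.25, CANX -0.14, NDUFV1 0.10, RPLP2 0.24, PAX2 0.13, PAX8 0.45, COL1A1 0.11, HIF1A -0.32 and VEGFA 0.24. In that fit IL6 was called lower (-0.34, adjusted p = 0.0104) and the fibroblast markers higher (median 1.62, adjusted p = 0.0190), while CSF1 (adjusted p = 0.0533) and HIF1A (adjusted p = 0.0678) were not called. The cause was not tested for any of the changes in this part except where the setting removes genes or libraries.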

Other observations

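Of the tests in this part, the codon usage test and the counts over other splits of the libraries were written before their results were seen, and the other tests were chosen afterwards. Genes outside the fixed lists, chosen after their values were seen, included long nuclear RNAs. MALAT1 rose from 506 ± 87.7 to 7673 ± 2847 CPM (SD, n = 3), a log2 fold change of 3.92 (adjusted for GC and length 2.99). NEAT1, the scaffold of paraspeckles, rose from 168 ± 24.9 to 1619 ± 357 CPM (3.27, adjusted 3.07), and KCNQ1OT1 rose by 2.86 (adjusted 0.97). FOXA2, a transcription factor of endodermal lineages, fell from 11.2 ± 1.54 to 0.465 ± 0.332 CPM (-4.57, adjusted -3.49).

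Fold change fell with the GC content of transcripts. The slope per percent GC was -0.109 for protein-coding genes and -0.0915 (95% interval -0.101 to -0.0817) for other genes, a share of 0.842. The other genes are all those not called protein coding, pseudogenes and antisense or overlapping RNAs included. Such genes may share reads with coding genes, so the similar slope cannot decide whether codon usage is the cause. A GC bias that varies from library to library may contribute, since libraries of the same line also differed along GC content, with an absolute rho of up to 0.544. A rank correlation gives no size, so how much of the trend between the lines such a bias could make was not tested. The labels name 0 library batches, so a batch that follows the groups cannot be told apart from the lines. A biological difference between the lines that follows GC content stays open and was not tested.

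Histone transcripts and short transcripts of RNA polymerase III fell together. The GC and length trend as fitted across genes did not remove the fall of the 59 histone genes tested. Their median log2 fold change was -2.20 before and -1.08 after adjustment (bootstrap 95% interval -1.41 to -0.97), with 57 lower. The adjustment moved single histone genes unevenly (HIST1H3A from -1.47 to -0.06, HIST1H2AC from -2.09 to -2.86). How well the fitted trend holds for histone transcripts was not tested, so the trend as the whole cause is not excluded. The bootstrap intervals in this part resample genes as if independent and leave out the spread between libraries. Fewer cells in S phase could account for the histones, but RMRP, RN7SK, RN7SL3 and RPPH1 had an adjusted median of -0.52 (range -1.08 to -0.14), with 3 of 4 lower, which decides neither way. Lower capture of RNA without a poly(A) tail cannot be told apart either, since 166 small nucleolar and Cajal body RNAs had an adjusted median of -0.21 (bootstrap 95% interval -0.39 to -0.08), with 42 lower and 20 higher.

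Some genes with large fitted decreases in the resistant line lie side by side. Among 14279 genes in order, 105 fell by 4 or more on the log2 scale and formed 3 adjacent pairs (LINC00261 and FOXA2, SMARCB1 and MIF, HIST1H2BB and HIST1H3C), against a mean of 0.764 in 10000 random orders (permutation p = 0.041). Linked loss of neighbouring genes may explain this, but it cannot be told apart from chance: leaving out each library, added after that p was seen, gave 2 pairs without control 2 (permutation p = 0.18) or control 3 (0.16), 3 without resistant 3 (0.061) or resistant 2 (0.04), 4 without control 1 (0.0099) and 6 without resistant 1 (permutation p = 2.0e-04). SMARCB1 reached 27.4 CPM in control 2 alone (1.14 and 0.884 in the others) and MIF 66.8 CPM in control 3 alone (1.52 and 1.61). This pair therefore rests on a single control library for each gene, and the count of 3 pairs and its permutation p include it. Random orders also ignore any shared regulation of neighbouring genes, from which the test cannot tell linked loss. Reads of HIST1H3C reassigned to near-identical copies cannot be told apart either, since counts summed over 13 H3 genes with HIST1H3C fell by 2.37 on the log2 scale, a difference of -0.21 from the median of 45 other histone genes (bootstrap 95% interval -0.49 to 5.0e-04) where its loss alone would give -0.15, and HIST1H3A had a log2 fold change of -1.47.

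The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In edgeR's test the real split gave 12683 changed genes, 8219 of them over 2-fold, and 9512 after GC and length adjustment. It was 1 of the 10 with as many, and the highest of the other splits was 0 for each count (94 genes at an unadjusted p under 0.05, and 148 after adjustment). Every other split places libraries of both lines in each group. The difference between the lines then adds to the spread within groups, so few calls had to follow. These gene counts therefore say nothing about chance. By camera the real split called 16 lists and the highest other split called 11. The other splits divide the lines unequally, so part of the difference between the lines stays in them. Their list calls therefore do not count false calls.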
